A study of Mus musculus with 8 samples.

How the data were processed

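RNA was measured in 8 samples of laser-captured duodenal villus epithelium from male C57BL/6J mice, 4 from atrophic villi 24 h after an injection of poly(I:C) and 4 from villi of saline-treated mice, 1 array each. Tissue was fixed in methacarn and embedded in paraffin, and the RNA was isolated, amplified as cDNA and labelled chemically with Cy5, per the labels' protocols. How the captured areas were chosen, how many mice were used and whether arrays share an animal are not given in the sources used here.

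The scanner files hold spot intensities in the red channel, made with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed intensity of each spot had spatial and multiplicative detrending but no background correction and no dye normalization, per the file headers, and the mean and background intensities are as scanned. The files name the mouse genome build mm9, and all coordinates printed are those of the probes in that build. The table of values deposited with the series holds log2 values, whose scale was not stated and was found from the data: 100% of its values lay within 0.001 of the log2 of a probe's mean processed intensity, so they carry no scaling between arrays. It lists 51488 of the 56605 probes of the design, and of the 5117 left out 0 were well above background on 5 or more arrays. Its column medians were 11.2, 11.1, 10.9 and 10.8 in atrophy and 10.6, 10.7, 10.4 and 10.3 in homeostasis. Partek is named in the submitters' processing notes with no role or version.

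Control spots and spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged. The log2 processed intensity was reduced by each array's 75th percentile. A probe was tested where it was well above background on at least 4 of the 8 arrays, in either group, which left 49525 probes. Each gene was represented by the probe with the highest mean over all arrays, which gave 32799 genes, 22527 of them with a RefSeq symbol. Array annotations can be old, so probes were matched by accession without version, then symbol, then synonym, to a RefSeq gene table of assembly GRCm38.p6, used for names only: 33919 matched by accession, 9866 by symbol and 283 by synonym, and 12537 kept the name in the files. Where a second probe of a named gene passed the threshold in the opposite direction, the text says so. A further probe that did not pass is not always mentioned. This holds for Ascl2, Gcg, Tac1, Sqle, Dhcr7 and Ifih1, among others.

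Genes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariates, two-sided, and Benjamini-Hochberg adjustment over all tested genes at 0.05. Where a gene was not well above background on any array of a group, the fold is a lower bound: the brighter group's mean against the dimmer group's mean of, on each array, the higher of the gene's own level and the lowest signal well above background. Group means are given with the SD over 4 arrays and differences with limma's SE. Separation of the groups was tested with an exact one-sided permutation test over the 35 splits of the arrays.

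The comparison, 31 gene lists with 708 distinct genes, the rule for named genes and the main alternatives were fixed before the data were examined. Of the list genes 690 were tested and 18 were not. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and with fry as alternatives, adjusted over all lists, where fry asks whether the genes of a list move on balance in a single direction and does not compare them with other genes. Counts of members are given over all tested genes and adjusted over the list alone. Named genes were the 12 largest rises and falls past the threshold among genes with a symbol, well above background on all 4 arrays of the higher group and with no overlap between the groups. To these came the 3 members of each list with the largest difference past the threshold, or the 2 largest each way where calls went both ways, the member with the smallest p where none passed, and a fixed set of Tlr3, Ifih1, Ifnb1, Ifnl2, Ifnl3, Clu, Msln, Olfm4, Lgr5, Mki67, Ada and Alpi. These parts gave 127 genes, of which the text prints the values of a part. Some genes that meet the rule are not reported here.

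Alternatives were quantile, median and cyclic loess normalization, no scaling, normexp background correction with an offset of 50, the series table as the source, no filter on dim probes or a filter on all 8 arrays, the mean of a gene's probes, eBayes with trend and robust settings, array quality weights, the replicate number as a block, each array left out in turn, a 2-fold minimum and an adjusted p under 0.01. An alternative with quantile normalization and without the homeostasis array 2 was added after the data were seen. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, tables handled in R with the data.table package, version 1.17.8, and figures drawn with matplotlib 3.10.9.

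The steps were tested on simulated data for the atrophy against homeostasis comparison, with 32762 genes of which 200 were changed. The fit recovered 18%, 56%, 76% and 76% of genes changed by 1, 2, 3 and 4 log2 units, with 6 false calls (5.04% of all calls). The real comparison called 31.25% of tested genes changed, a far larger share than was simulated. These recovery rates therefore need not hold for it. A list shifted by 2 log2 units was recovered, and 0 of 30 other lists were called. The simulated genes varied independently of each other. In the real data the estimated correlation was 0.35 for interferon-stimulated genes and 0.267 for cell cycle genes. The simulation therefore does not show how often lists of correlated genes are called falsely at the preset correlation.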

Results

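Gene expression was measured on 8 single-colour microarrays of RNA from duodenal villus epithelium, which had been collected by laser capture, a method that lifts chosen areas off a tissue section under a microscope. The mice were C57BL/6J males aged 8 weeks. In the atrophy group, 4 arrays came from mice that had received 20 mg/kg of poly(I:C), a synthetic double-stranded RNA that triggers antiviral signalling, into the peritoneum 24 h before the tissue was taken. The other 4 arrays, the homeostasis group, came from mice that had received saline. The labels do not tie the arrays to separate animals, so the p-values below measure the spread between these samples, which may be partly technical, and they would be too small if arrays shared an animal.

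Each array held 62976 spots, 3671 of them controls, and 0 spots were saturated. Probes well above background made up 88.4% ± 1.30 of the design in atrophy and 80.6% ± 4.62 in homeostasis (SD, n = 4). The median signal per probe ran from 1648 to 2051 intensity units in atrophy and from 1056 to 1441 in homeostasis. The number of arrays limits the precision of every value.

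The comparison asked how gene expression in the villus epithelium differed between villus atrophy and homeostasis. In atrophy, genes of digestion, absorption and detoxification fell together: 23 of 26 brush-border genes, 20 of 22 nutrient transporters and 27 of 27 genes of xenobiotic metabolism were lower, with median log2 differences of -3.33, -3.66 and -3.65. Lct, which encodes the milk-sugar enzyme lactase, fell from 4.23 ± 0.17 to -4.24 ± 1.51 log2 units relative to the array's 75th percentile (SD, n = 4), and was well above background on 3 of 4 atrophy arrays. Genes of fetal-like and regenerative epithelium rose, 24 of 28 of them, with a median of 3.40. Clu, which encodes the secreted chaperone clusterin, rose from -2.91 ± 0.40 to 3.80 ± 0.37 (SD, n = 4), a 105-fold difference. Interferon-stimulated genes, cell cycle genes and enteroendocrine markers were also higher, in 29 of 32, 24 of 30 and 14 of 23 measured members. With an estimated correlation the list calls were lost for interferon-stimulated genes and cell cycle genes (adjusted p = 0.151 for each) and for nutrient transporters (adjusted p = 0.0775), and the other 4 lists named here kept theirs.

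Among 32799 tested genes, limma called 10251 changed at an adjusted p under 0.05, of which 5698 were higher and 4553 lower in atrophy. Of these, 4237 higher and 3495 lower genes carried a gene symbol. A difference of at least 2-fold was found for 4091 of the higher and 2813 of the lower genes, and at least 8-fold for 674 and 521. The arrays of the groups did not overlap for 11139 genes, 34% of those tested, where chance would give 2.86%. Arrays correlated better with their own group (mean r = 0.934) than with the other (mean r = 0.851), a difference of 0.0824 with an exact one-sided permutation p = 0.0286 over 35 splits, the smallest p that 4 against 4 arrays can give.

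**Figure D1:**
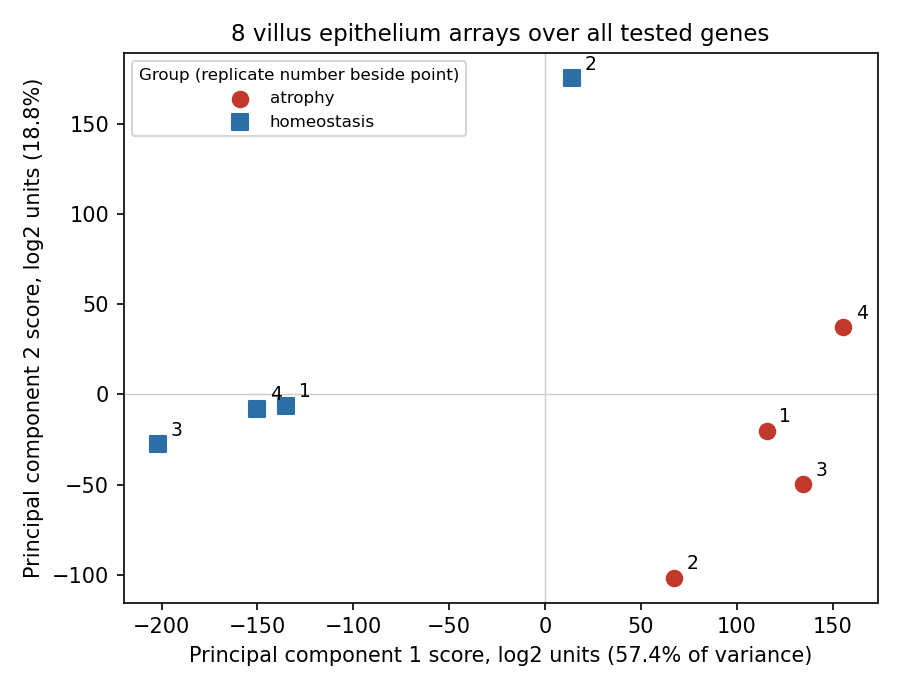
The 8 arrays by their scores on principal components 1 and 2 (log2 units, all tested genes), with circles for atrophy, squares for homeostasis and replicate numbers beside the points. Component 1 held 57.4% of the variance, and the homeostasis array 2 lay at 14.1 on it and at 176 on component 2, apart from the other 3 homeostasis arrays.

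The homeostasis array 2 correlated at 0.894 to 0.907 with the other homeostasis arrays, which correlated with each other at 0.973 or more. Without this array, 10212 genes were higher and 4840 lower. The share of changed genes that were higher was 55.6%, and it was 38.2% when arrays were scaled to their median and 78.5% with no scaling. Both groups lay in separate rows of 1 slide, so the row of the slide and the group cannot be told apart. Dim genes read higher in atrophy: the median log2 difference was 0.98 in the dimmest of 5 equal classes of genes and -0.04 in the brightest.

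The median log2 difference of all genes was 0.29, and list medians are also given relative to it. Other scalings moved this median by -0.225 (quantile), -0.334 (median), -0.235 (cyclic loess), 0.296 (none) and -0.116 (normexp background). The medians of the 18 lists called below kept their sign under each of these 5. Of 31 gene lists, 10 were higher and 8 lower by limma's camera with a preset correlation of 0.01. With a correlation estimated from the data, 6 calls held: those of fetal-like epithelium, enteroendocrine cells, brush border, lipid absorption, duodenal micronutrient uptake and xenobiotic metabolism.

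**Figure D2:**
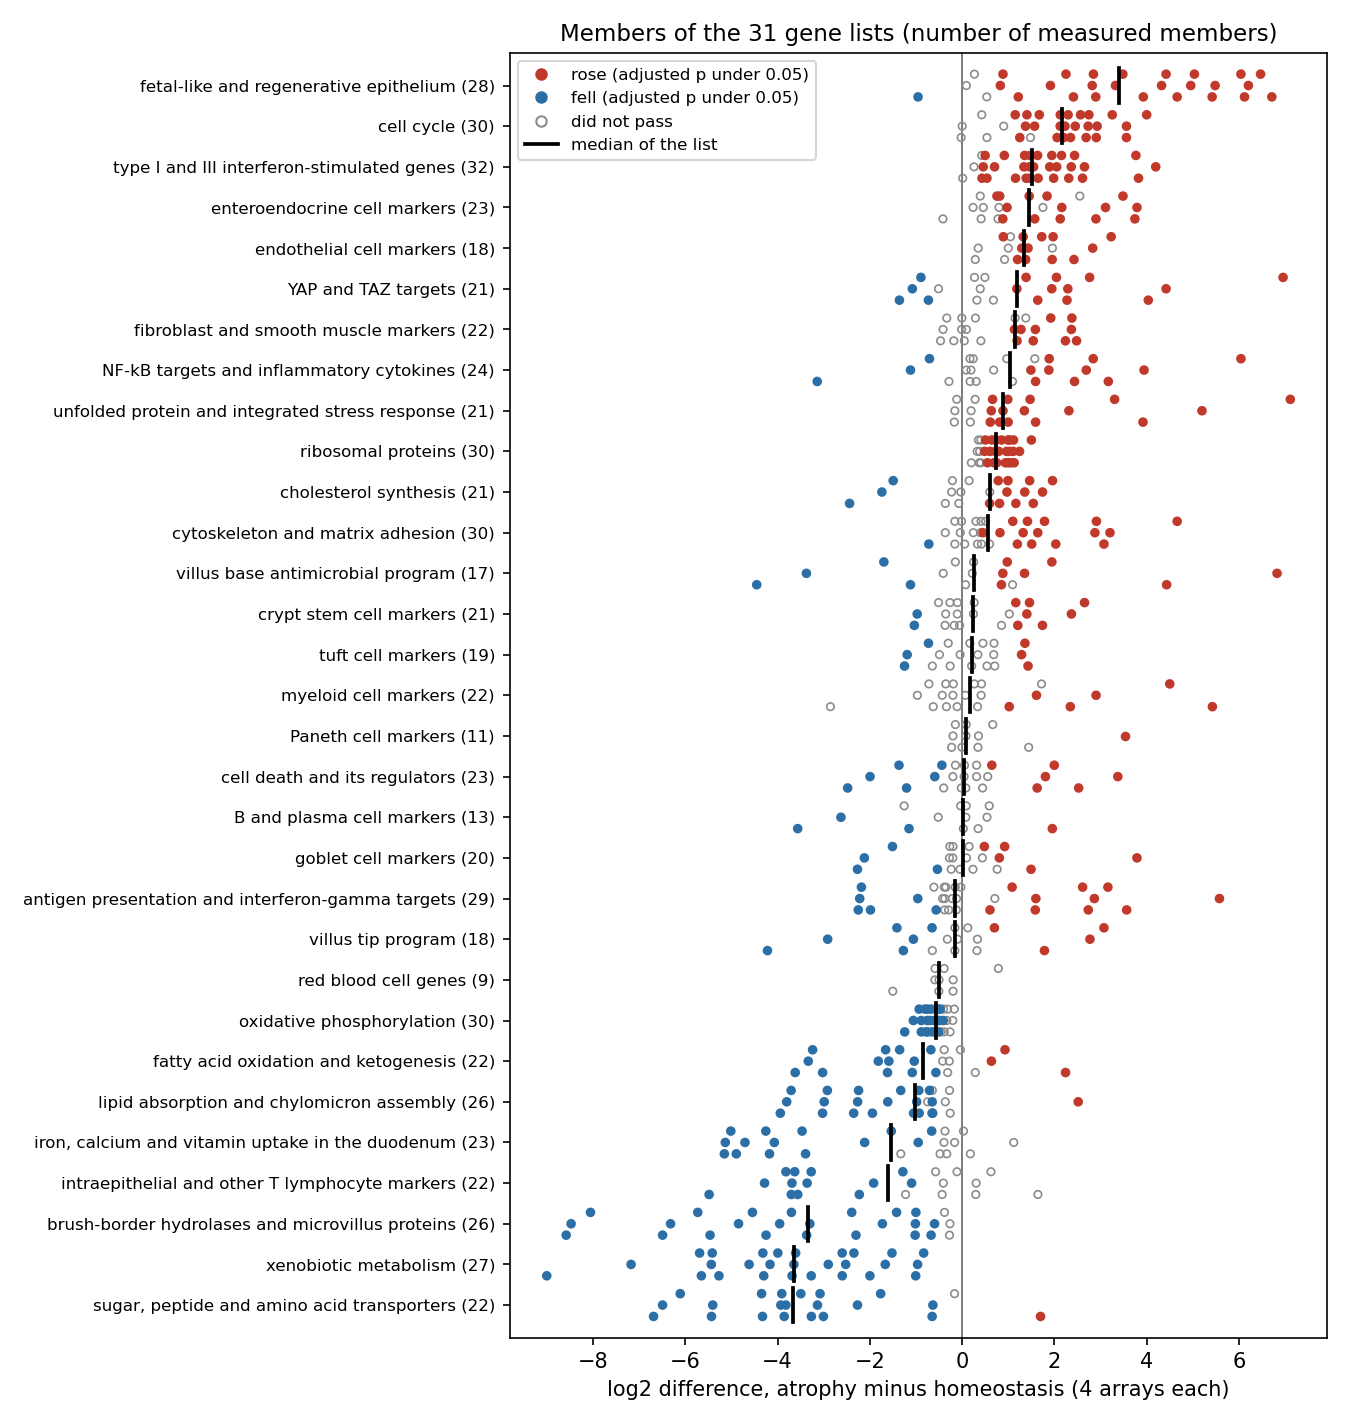
Log2 differences (atrophy minus homeostasis, 4 arrays each) of every measured member of the 31 lists, ordered by list median, with the number of members in brackets. Filled points passed an adjusted p of 0.05, open points did not, and vertical bars mark list medians, which ran from -3.66 for nutrient transporters to 3.40 for fetal-like epithelium. The medians of 10 lists that camera did not call, among them antigen presentation, cell death, villus tip and crypt stem cells, changed sign under some scalings.

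Among single genes with symbols, several of the largest rises were in genes with little or no signal in homeostasis. The annexin gene Anxa8 was at least 68.4-fold higher, where the bound sets the atrophy mean against the lowest signal well above background on each homeostasis array, and 1 homeostasis array read apart from the other 3. The same kind of bound gave at least 57.0-fold for Phlda2 and at least 39.1-fold for Pbp2. Fosl1, a subunit of the AP-1 transcription factor, rose by 7.63 log2 units (adjusted p = 9.49e-05) and was well above background on 2 of the 4 homeostasis arrays. Tcf23 rose by 8.33 and was well above background on 2 of those arrays, and Dmkn (dermokine) rose by 7.86 with 1 of them. Chac1, an enzyme that degrades glutathione, was measured on all 8 arrays and rose 138-fold.

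Several of the largest falls lay in genes of enzymes. Rdh7, a retinol dehydrogenase gene (mm9, chromosome 10, 127321262 to 127321321), fell by 9.69 log2 units, from 2.83 ± 0.04 to -6.85 ± 1.42 (SD, n = 4), and was well above background on 1 of 4 atrophy arrays. Ces1f, a carboxylesterase gene, fell from 2.13 ± 0.11 to -6.87 ± 1.43 (SD, n = 4) and was likewise measured on 1 atrophy array. Treh (trehalase) fell by 8.58 and Naaladl1 (a brush-border peptidase) fell by 8.05, each measured on 3 atrophy arrays, with 1 atrophy array apart from the other 3 in Treh. Pck1, an enzyme of glucose synthesis, fell 148-fold and was measured on all arrays, as was Cym, the gene of the milk-clotting protease chymosin, which fell 150.4-fold. The transcription factor gene Klf15 was not well above background on any atrophy array and was at least 32.2-fold lower.

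Interferon-stimulated genes, the antiviral effectors and sensors that type I and III interferons switch on, rose in 29 of 32 measured members and fell in 0, with 3 not past the test (30 and 0 adjusted over the list alone). Their median was 1.51, or 1.22 above that of all genes (adjusted p = 3.68e-12). With an estimated correlation the adjusted p = 0.151. Ifit2, which restrains translation of viral RNA (mm9, chromosome 19, 34650244 to 34650303), rose from -5.48 ± 0.59 to -1.29 ± 0.48 (SD, n = 4), and 1 of 4 homeostasis arrays read it well above background. Oas2, an oligoadenylate synthetase, rose 14.1-fold (adjusted p = 3.28e-05), and Ifi44 rose 13.6-fold (adjusted p = 0.000636).

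Tlr3 and Ifih1, receptors for poly(I:C), moved little. The log2 difference was -0.40 ± 0.17 (SE) for Tlr3, the endosomal sensor, with adjusted p = 0.104. Ifih1, the cytosolic sensor MDA5, rose by 0.46 ± 0.12 (adjusted p = 0.0241), a call that was lost when arrays were scaled to their median (difference 0.12). Ifnb1, the interferon beta gene, was at least 2.19-fold higher (adjusted p = 0.00267), since it was not well above background on any homeostasis array, and this call was lost with quantile normalization (adjusted p = 0.111). Ifnl3, an interferon lambda gene, read -0.60 ± 0.19 (adjusted p = 0.0454), a call lost in most leave-one-out runs, and Ifnl2 was not tested.

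Genes of antigen presentation and interferon-gamma response divided: 10 of 29 rose, 6 fell and 13 did not pass (11 and 9 adjusted over the list alone). The list passed no test (adjusted p = 0.604), and its median of -0.15, its mean of 0.43 and its tests differed in sign, with the median above 0 under quantile normalization and no scaling. Cxcl10, a chemokine that attracts T lymphocytes (mm9, chromosome 5, 92775781 to 92775840), rose 47.6-fold, from -3.44 ± 0.80 to 2.14 ± 0.24 (SD, n = 4). Gbp3, a guanylate-binding protein, rose 11.8-fold. H2-Ab1, a chain of the class II antigen-presenting complex, fell by 2.25 log2 units, and Ciita, the class II transactivator, fell by 2.22 (adjusted p = 0.00146 and 0.00154).

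NF-kB targets and inflammatory cytokines rose in 10 of 24 members and fell in 3 (11 and 3 adjusted over the list alone), with a median of 1.03 and adjusted p = 0.0215. The median was 0.52 with quantile normalization, 0.56 with cyclic loess, 0.55 with normexp background correction and 0.30 with only genes well above background on all arrays. The adjusted p = 0.205 with an estimated correlation, 0.102 without the homeostasis array 2, 0.0584 without the atrophy array 2, 0.0531 with no scaling, and 0.0627 with only genes well above background on all arrays. Lcn2, which withholds iron from bacteria, rose 15.4-fold (adjusted p = 2.10e-05), with 1 homeostasis array apart from the others, and Cxcl1, a neutrophil chemokine, rose by 6.04 log2 units, with 1 of 4 homeostasis arrays well above background. Il15, a cytokine that sustains intraepithelial lymphocytes, fell 8.82-fold, from 1.21 ± 0.20 to -1.93 ± 0.27 (SD, n = 4). Il18 fell by 1.12 (adjusted p = 0.0182), a call lost with no scaling (adjusted p = 0.0695).

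Genes of cell death went both ways, 6 of 23 up and 6 down (7 and 7 adjusted over the list alone), and the list passed no test (adjusted p = 0.757), with a median of 0.05 and a mean of 0.21 against tests pointing down, and a median below 0 under median scaling. The members that rose most belong to necroptosis: Ripk3, its upstream kinase, rose 10.4-fold and Mlkl, which permeabilises the membrane, rose 5.75-fold (adjusted p = 0.000169 and 0.000361). The death receptor gene Fas fell 3.99-fold (adjusted p = 0.000255).

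Genes of the unfolded protein and integrated stress response rose in 15 of 21 members and fell in 0 (15 and 0 adjusted over the list alone), with a median of 0.88, or 0.59 above all genes, and adjusted p = 2.33e-05. Under median scaling 8 members rose and the median was 0.55. The adjusted p = 0.155 with an estimated correlation. Besides Chac1, Psat1, an enzyme of serine synthesis, rose 36.6-fold with 1 atrophy array slightly apart, and the transcription factor gene Atf3 rose 15.1-fold (adjusted p = 0.000498).

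Fetal-like and regenerative epithelium, genes known from fetal gut and from repair after injury, rose in 24 of 28 members, and 1 fell (25 and 1 adjusted over the list alone). The list median lay 3.11 above all genes (adjusted p = 9.32e-13, and adjusted p = 0.0432 with an estimated correlation). Clu (mm9, chromosome 14, 66600325 to 66600384) had an adjusted p of 9.90e-06. Msln, the surface protein mesothelin, rose by 6.47 ± 0.75 log2 units (SE, adjusted p = 0.000600) to 3.91 ± 0.09 (SD, n = 4). Gja1, the gene of connexin 43, read -0.96 with its brightest probe, but 3 of its 8 probes were called in the opposite direction, and the mean over its probes was higher in atrophy by 1.33.

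YAP and TAZ targets rose in 11 of 21 members and fell in 4 (12 and 5 adjusted over the list alone), with a median of 1.18. Camera did not call the list (adjusted p = 0.0525), though fry did (adjusted p = 5.28e-05), and camera called it with quantile normalization (adjusted p = 0.0146), median scaling (0.0176) and cyclic loess (0.0154) and not with no scaling (0.0612), array quality weights (0.101) or without the homeostasis array 2 (0.102). F3, the gene of tissue factor, rose 21.4-fold (adjusted p = 1.49e-05), and Ajuba, an adhesion adaptor, rose by 6.95 log2 units with 1 of 4 homeostasis arrays well above background. Nuak2, a kinase gene, fell 2.57-fold, with 1 atrophy array apart. Cytoskeleton and matrix adhesion genes rose in 15 of 30 members and fell in 1 (19 and 1 adjusted over the list alone), with a median of 0.55, or 0.26 above all genes, and adjusted p = 4.06e-05. Under median scaling 10 members rose and the list median was 0.22 (adjusted p = 0.00345). With an estimated correlation the adjusted p = 0.195. Lama3, a laminin chain of the basement membrane, rose 9.21-fold (adjusted p = 0.000462). Itgb6, an integrin of remodelling epithelia that was also on the villus tip list, rose 8.41-fold, and the adhesion protein gene Zyx fell by 0.72, a call lost with no scaling (adjusted p = 0.193).

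Brush-border hydrolases and microvillus proteins fell in 23 of 26 members and rose in 0, with 3 not past the test (23 and 0 adjusted over the list alone). Relative to all genes their median was -3.63 (adjusted p = 3.43e-19, and adjusted p = 0.0432 with an estimated correlation). Lct (mm9, chromosome 1, 130181389 to 130181448) had an adjusted p of 0.000117. Alpi, the intestinal alkaline phosphatase gene, fell less, from 5.35 ± 0.12 to 4.35 ± 0.27 (SD, n = 4, adjusted p = 0.00365).

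Transporters of sugars, peptides and amino acids fell in 20 of 22 members and 1 rose (20 and 1 adjusted over the list alone). The adjusted p = 1.25e-17, and the adjusted p = 0.0775 with an estimated correlation. Slc5a11, a sodium and inositol cotransporter gene (mm9, chromosome 7, 130416704 to 130416763), fell 103-fold, from 3.66 ± 0.10 to -3.03 ± 0.82 (SD, n = 4). Slc13a2, a citrate transporter gene, fell 89.9-fold (adjusted p = 1.02e-05). Slc38a2, an amino acid transporter of stressed and growing cells, was the member that rose, by 1.70 (adjusted p = 0.00244).

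Lipid absorption and chylomicron assembly fell in 20 of 26 members and rose in 1 (22 and 1 adjusted over the list alone), with a median of -1.02 (adjusted p = 3.69e-12, and adjusted p = 0.0432 with an estimated correlation), and 14 fell with no scaling. Apoc3, a lipoprotein component, fell 13.9-fold (adjusted p = 0.00120), and Cd36, a fatty acid receptor, fell by 3.94 with 3 of 4 atrophy arrays well above background. Plin2, which coats lipid droplets, rose 5.71-fold (adjusted p = 9.14e-05). Fatty acid oxidation and ketogenesis fell in 13 of 22 members and rose in 3 (13 and 3 adjusted over the list alone), with a median of -0.86 and adjusted p = 1.85e-06. The adjusted p = 0.151 with an estimated correlation. Hadh, a dehydrogenase of this pathway, fell 12.3-fold from 4.46 ± 0.13 to 0.84 ± 0.26 (SD, n = 4), and Ppara, the nuclear receptor that controls it, fell 10.1-fold. Acot1, a thioesterase gene, rose 4.72-fold, with 1 homeostasis array apart from the other 3.

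Duodenal uptake of iron, calcium and vitamins fell in 14 of 23 members and rose in 0, with 9 not past the test (16 fell and 1 rose adjusted over the list alone). The median was -1.54 (adjusted p = 8.71e-10, and adjusted p = 0.0459 with an estimated correlation). Cubn, the receptor for the vitamin B12 complex, fell 35.6-fold (adjusted p = 1.22e-05), Slc30a10, a manganese exporter, fell 32.3-fold with 1 homeostasis array apart, and Lrat, which esterifies retinol, fell by 5.13 with 2 of 4 atrophy arrays well above background.

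Xenobiotic metabolism fell in all 27 measured members (27 adjusted over the list alone), with a median of -3.94 relative to all genes (adjusted p = 5.93e-25, and adjusted p = 0.0432 with an estimated correlation). Cyp3a11, a cytochrome P450 of drug oxidation, fell 51.6-fold, from 5.08 ± 0.16 to -0.61 ± 1.15 (SD, n = 4, adjusted p = 0.000218), with 1 homeostasis array slightly apart. Cyp2b10, another P450 gene, fell 144-fold (adjusted p = 1.38e-05). Oxidative phosphorylation genes fell in 22 of 30 members and rose in 0 (25 and 0 adjusted over the list alone) by a smaller amount, with a median of -0.58, or -0.87 relative to all genes (adjusted p = 1.31e-11). The adjusted p = 0.0991 with an estimated correlation, and 4 members fell with no scaling, where the list median was -0.28. The subunits Sdhc, Sdha and Sdhd of the succinate dehydrogenase complex fell by 1.24, 1.06 and 0.93.

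Cholesterol synthesis genes rose in 11 of 21 members and fell in 3 (11 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.302), while limma's fry, which does not compare a list with other genes, called it higher (adjusted p = 0.0353), with 3 members up and 3 down under median scaling. Sqle, which encodes squalene epoxidase, rose 3.88-fold, and Stard4, a cholesterol carrier, fell 3.34-fold (adjusted p = 0.000106 and 0.000265). Dhcr7, which encodes the enzyme of the last step, fell 5.42-fold with 1 homeostasis array apart from the other 3.

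Genes of the villus tip and base moved in both directions, and camera called neither list. In the villus tip program 4 of 18 members rose and 6 fell (4 and 6 adjusted over the list alone, adjusted p = 0.193 with camera and 0.0432 with fry, which called it lower), with a median of -0.16 that was above 0 with no scaling. Ada, adenosine deaminase, fell 2.67-fold from 4.68 ± 0.19 to 3.27 ± 0.20 (SD, n = 4, adjusted p = 0.000617), and Enpp3, a nucleotide-degrading enzyme, fell 18.6-fold, while Egfr, the epidermal growth factor receptor, rose 6.81-fold. In the villus base antimicrobial program 7 of 17 rose and 4 fell (7 and 4 adjusted over the list alone, adjusted p = 0.784 with camera and 0.00611 with fry, which called it higher), with a median of 0.25 that was below 0 under median scaling. Its risers were led by the hydrogen peroxide-producing pair of Duox2, up 21.5-fold, and its maturation factor Duoxa2, up by 6.82 log2 units with 2 of 4 homeostasis arrays well above background. The Reg family lectin Reg3a fell 21.9-fold and Reg1 fell 10.4-fold (adjusted p = 0.000624 and 0.000681).

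Cell cycle genes rose in 24 of 30 members and fell in 0 (26 and 0 adjusted over the list alone), with a median of 2.16 and adjusted p = 1.95e-09. The adjusted p = 0.151 with an estimated correlation. Ccna2, cyclin A2 (mm9, chromosome 3, 36464929 to 36464988), rose 16.0-fold, from -2.70 ± 1.37 to 1.30 ± 0.14 (SD, n = 4). Cdc20, an activator of mitotic exit, rose 11.8-fold, and Mki67, the proliferation marker Ki-67, rose 6.43-fold (adjusted p = 0.000664 and 0.00210). Crypt stem cell markers as a list were not called by camera (7 of 21 up, 2 down, the same counts adjusted over the list alone, adjusted p = 0.531) and were called higher by fry (adjusted p = 0.000114), and their median of 0.24 was below 0 under median scaling and cyclic loess. Olfm4 and Lgr5, markers of crypt base stem cells, had log2 differences of -0.06 ± 0.64 (adjusted p = 0.955) and 1.02 ± 0.55 (SE, adjusted p = 0.194), and Lgr5 passed with the mean of its probes (adjusted p = 0.000838). Ephb2, a receptor of crypt cells, rose 5.16-fold, and Ascl2, a stem cell transcription factor gene, rose 6.28-fold (adjusted p = 0.000106 and 0.00404). The share of crypt cells in the captured areas was not measured, so its part in the cell cycle rise is untested. Over homeostasis arrays 1 to 4 the cell cycle means (-1.19, -1.49, -2.08 and -1.38) and Paneth list means (1.42, 0.69, -0.28 and 1.09) had the same order. Over the atrophy arrays their orders differed.

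**Figure D3:**
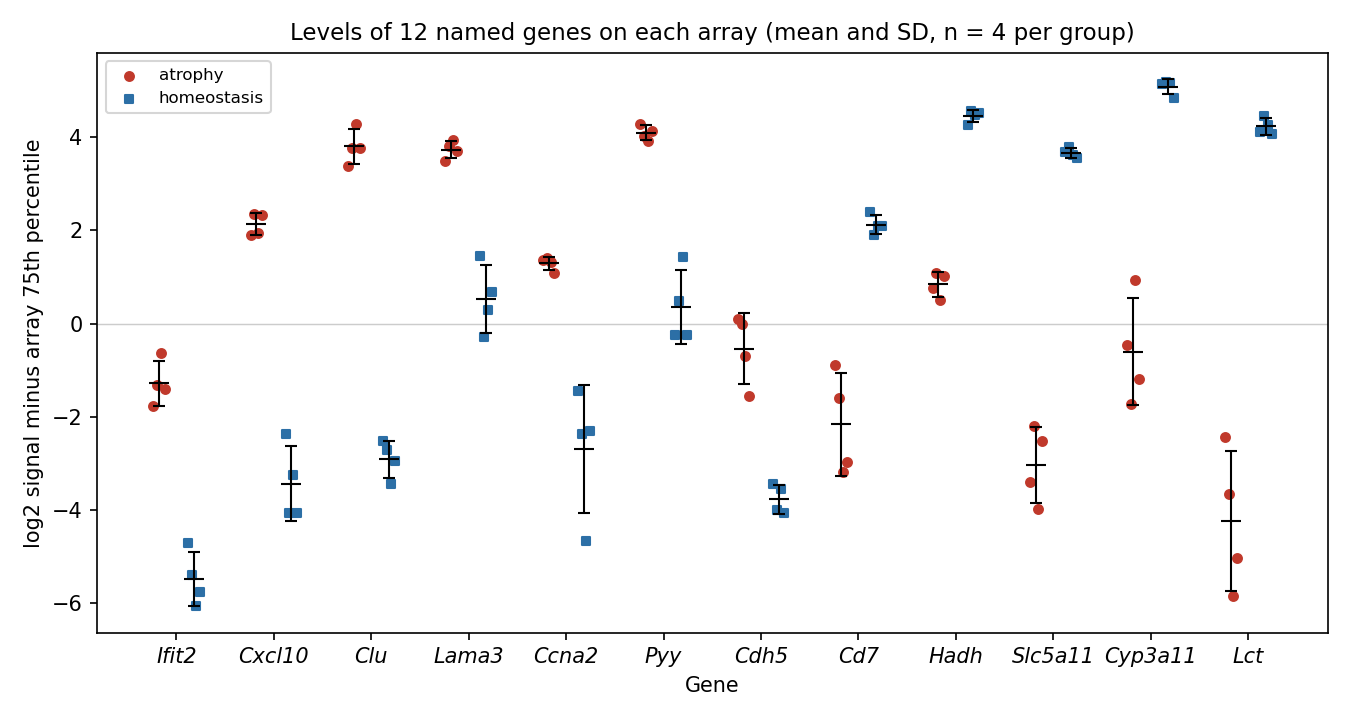
Levels of 12 named genes on each array (log2 signal minus the array's 75th percentile), with circles for atrophy, squares for homeostasis, and bars for the mean and SD of 4 arrays. For each of these genes all 4 arrays of the groups lie apart: Clu has means of 3.80 and -2.91, and Lct has means of -4.24 and 4.23 in atrophy and homeostasis.

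Among secretory cells, enteroendocrine markers rose in 14 of 23 members and fell in 0 (17 and 0 adjusted over the list alone), with a median 1.16 above all genes (adjusted p = 1.13e-05, and adjusted p = 0.0484 with an estimated correlation), and 9 members rose under median scaling. The hormone genes Pyy (peptide YY), Gcg (proglucagon) and Tac1 (tachykinins) rose 13.4-fold, 11.2-fold and 13.8-fold, and Pyy went from 0.35 ± 0.79 to 4.09 ± 0.16 (SD, n = 4). Goblet cell markers passed no test (5 of 20 up, 4 down, the same adjusted over the list alone, adjusted p = 0.624). Their median of 0.02 and mean of 0.07 stood against tests pointing down, and the median was below 0 under median scaling. Retnlb, a goblet cell antimicrobial protein, rose 13.8-fold, and Ccl6 fell 4.82-fold. In the Paneth list 1 of 11 members passed, Mmp7, a matrilysin that processes defensins, up 11.6-fold (1 adjusted over the list alone, list adjusted p = 0.784), and its median of 0.09 was below 0 under median scaling. Tuft cell markers had 3 members up and 3 down of 19 (3 and 3 adjusted over the list alone, adjusted p = 0.907), and their tests differed in sign, with a median of 0.20 that was below 0 under median scaling and cyclic loess. Trpm5, the tuft cell cation channel, rose 2.69-fold, a call lost with the mean of its probes (adjusted p = 0.130).

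Markers of other cell types in or under the epithelium also moved. Markers of intraepithelial and other T lymphocytes fell in 13 of 22 members and rose in 0 (17 and 1 adjusted over the list alone), with a median of -1.60 (adjusted p = 9.65e-08). With an estimated correlation the adjusted p = 0.0788. Cd7 fell 19.5-fold from 2.12 ± 0.20 to -2.16 ± 1.11 (SD, n = 4), the granule protease gene Gzmb fell 14.1-fold, and Cd3g, part of the T cell receptor complex, fell by 5.48 with 2 of 4 atrophy arrays well above background. Endothelial markers rose in 12 of 18 members and fell in 0 (12 and 0 adjusted over the list alone), with a median of 1.35 (adjusted p = 0.000198). The adjusted p = 0.322 with an estimated correlation, and 8 members rose under median scaling. Cdh5, the cadherin of endothelial junctions, rose 9.37-fold, and the receptor gene Tie1 rose 7.10-fold (adjusted p = 0.000665 and 0.00228). Fibroblast and smooth muscle markers rose in 10 of 22 members and fell in 0 (12 and 0 adjusted over the list alone, median 1.14, adjusted p = 0.0351), with adjusted p = 0.625 with an estimated correlation, 0.0505 under median scaling, where 6 members rose, 0.106 with no scaling, 0.0602 with no filter on dim probes and 0.142 with array quality weights. Leaving out 1 array also ended the call, with adjusted p = 0.0524 without the atrophy array 1, 0.103 without the atrophy array 2, 0.229 without the homeostasis array 2 and 0.110 without the homeostasis array 3. The risers included the platelet-derived growth factor receptors Pdgfra and Pdgfrb, up 5.15-fold and 5.57-fold.

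Myeloid markers passed no test as a list (6 of 22 up, 0 down, the same adjusted over the list alone, adjusted p = 0.704, median 0.17 and below 0 under median scaling). Mrc1, the macrophage mannose receptor, rose 7.47-fold, and the neutrophil protein gene S100a8 rose by 4.50 with 1 of 4 homeostasis arrays well above background. B and plasma cell markers passed no test either (1 of 13 up and 3 down, 1 and 4 adjusted over the list alone, adjusted p = 0.240), with a median of 0.03 against a mean of -0.43, and a median below 0 under quantile, median and cyclic loess scaling. Jchain, which links antibodies of plasma cells, fell 11.8-fold (adjusted p = 0.00105). Red blood cell genes had 0 of 9 members past the test, also adjusted over the list alone, and an adjusted p of 0.271. The member with the smallest p, Slc4a1, read -0.59 ± 0.38 (SE, adjusted p = 0.272), with 1 homeostasis array apart.

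Ribosomal protein genes rose in 23 of 30 members and fell in 0 (29 and 0 adjusted over the list alone), by small amounts, with a median of 0.74, or 0.45 above all genes, and adjusted p = 1.92e-08. The adjusted p = 0.195 with an estimated correlation, and 2 members rose under median scaling, where the list median was 0.41. Rpl8 rose 2.37-fold (adjusted p = 0.00762), with 1 homeostasis array apart from the other 3, and Rpl14 rose 2.18-fold, and both calls were lost under median scaling (adjusted p = 0.115 and 0.0693).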

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

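Of the tests in this part, those on dim genes, endothelial markers and T lymphocyte markers were chosen only after the result was seen, while the splits of the samples had a prediction written before their values were read. For dim genes, 3 earlier tests were run, seen and then dropped. The first set the signal range of an array against its dim level, which measure nearly the same thing, and the second read the slide row from the homeostasis array 2 alone. The third used the processed signal of the negative control spots, which lay between 24.6 and 25.3 intensity units on every array and so could not move.

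A count of the other ways to split the 8 arrays into 4 and 4 asked whether the number of changed genes could arise by chance. The real split gave 10251 genes and was the only 1 of 35 to give as many, which argues against chance. It does not exclude chance, since 1 of 35 is the smallest share these splits can give. The real split is also the split by row of the slide. The highest other count was 3385, in the split that exchanged the homeostasis array 2 for the atrophy array 2. Which genes made up that count was not tested.

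Dim genes read higher in atrophy, by 0.92 ± 0.47 log2 units (SE) in the dimmest of 5 equal classes. The negative control spots gave no sign of a higher background on the atrophy arrays. In unprocessed intensity units they shifted by -29.9 ± 42.9, the dimmest class was higher in atrophy by 169 ± 47.6, and the 2 shifts differed by 199 ± 57.5 (SE). The background beside the spots had medians of 114 ± 3.92 in atrophy and 106 ± 2.25 in homeostasis (SD, n = 4). The size of the difference of 199 does not decide the cause. Genes of the class were kept for signals well above background on at least 4 arrays, and control spots were not. More probes reached that level in atrophy (88.4%) than in homeostasis (80.6%). The median log2 difference of all genes was 0.291, against 0.157 with a filter on all arrays and 0.304 with no filter. The dimmest class was not compared under these filters. The row of the slide cannot be told apart from the group, because 0 of the 2 rows held arrays of both groups. A wider set of transcripts at low levels in atrophic epithelium may contribute and stays untested, as do differences in RNA amount or amplification, which the sources used here do not give. The median of these genes ranged from -4.84 to -3.83 on the atrophy arrays and from -5.98 to -5.29 on 3 homeostasis arrays, and the homeostasis array 2 lay within the atrophy range.

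Endothelial markers rose by a median of 1.35. The shift of dim genes is argued against as the whole cause, because the list median lay at percentile 99.99 of 10000 random lists with the same mean levels. An equal rise of every kind of lamina propria cell in the captured tissue is also argued against. The endothelial shift exceeded that of smooth muscle markers by 1.64 ± 0.26 and that of B and plasma cell markers by 1.94 ± 0.363 (SE). More captured lamina propria with unequal shares of its cells is not argued against. The smooth muscle markers, set apart after the data were seen, were Acta2, Tagln, Myh11, Des, Actg2 and Cnn1. They are 6 of the 22 members of the fibroblast and smooth muscle list. That list rose as a whole, with a mean of 0.91. Over atrophy arrays 1 to 4 the means of the endothelial (-0.23, -0.25, -1.03 and -1.46), fibroblast and smooth muscle (0.84, 1.03, 0.54 and 0.20) and myeloid lists (0.99, 0.58, 0.28 and 0.22) were lower on arrays 3 and 4 than on arrays 1 and 2. The same held for T lymphocyte markers (-1.74, -1.92, -2.10 and -2.16) and red blood cell genes (-2.23, -2.24, -2.85 and -2.85). It did not hold for B and plasma cell markers (-1.61, -1.67, -2.35 and -1.38). So this order was not particular to stromal lists. A candidate explanation that stays open is a larger and varying share of stroma with endothelium, fibroblasts and myeloid cells in the captured tissue, or a change within these cells, and the row of the slide stays open here too.

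T lymphocyte markers fell by a median of 1.60. The scaling is argued against, since the list median lay at percentile 0 of 10000 lists with the same mean levels, that is, below all of them. The shift of dim genes ran upward in atrophy, and the medians of these random lists had a mean of 0.234. That shift could not give a fall, so the comparison was no test of it. An equal fall of every kind of leukocyte in the captured tissue is argued against as well. The shift of T lymphocyte markers lay below that of myeloid markers by more than its error, with a difference of -2.52 ± 0.147 (SE). The B and plasma cell markers shifted by -0.426 ± 0.238 (SE), and a larger share of stroma, left open above, may raise the myeloid list. A smaller loss of other leukocytes is therefore not excluded. Fewer intraepithelial lymphocytes in atrophic epithelium, or lower marker levels per cell, may account for the fall, and these data do not separate them.

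In 324 groups of 4 arrays, made of named genes, list means and 4 measures of the arrays, 23 had an array whose gap to its nearest neighbour took up an unusually large part of the group's range (Dixon's ratio), where chance gives about 1 in 20 groups. The homeostasis array 2 was the array that stood apart in 10 of them. It read higher than the other 3 for Anxa8 (ratio 0.898), Stc1 (0.947), Cxcl1 (0.896), Ajuba (0.937), the mean of the brush-border list (0.953) and the mean of the lipid absorption list (0.855). It read lower for Duoxa1 (0.856), Dhcr7 (0.858), Plcg2 (0.842) and Rpl8 (0.877). Other homeostasis arrays stood apart for Fosl1 (array 4, 0.899), Lcn2 (array 1, 0.835), Gja1 (array 1, 0.918), Acot1 (array 3, 0.862), Slc30a10 (array 1, 0.866), Cyp3a11 (array 4, 0.863) and Slc4a1 (array 3, 0.858). The atrophy array 3 stood apart for Treh (0.881), Psat1 (0.890), Ajuba (0.870) and Nuak2 (0.884). In 2 more groups the ratios were 0.867 and 0.869.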

How the results depend on the processing

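The setting without the homeostasis array 2 and with quantile normalization was the only alternative chosen after the data were seen. Signal over background limits the values of genes that were not well above background on every array of a group. Group separation, which was not computed for the variance models and the block, ran from 0.0586 with no filter on dim probes to 0.0968 with a filter on all arrays, with the same exact p.

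Calls in the same direction as at first were shared for 87% of the 10251 genes with quantile normalization, 90.1% with cyclic loess, 73.1% with median scaling, 79.4% with no scaling and 94.2% with normexp, with 0 opposite calls in these 5, 13 with the mean of probes and 2 with quantile normalization and without the homeostasis array 2. Median scaling gave 3279 higher genes, no scaling gave 8961 higher and 2457 lower, and array quality weights gave 18417 changed and 12141 higher. Adding a 2-fold minimum left 2813 lower genes, and an adjusted p under 0.01 left 6047 changed, 3157 higher and 2890 lower, since these are stricter thresholds. For the scalings and the weights the cause was not tested. Quantile normalization without the homeostasis array 2 gave 6953 higher and 5984 lower genes.

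With the replicate number as a block, 6070 genes changed, 3266 higher and 2804 lower, and 11 lists were higher and 8 lower. Same-numbered samples deviated from their group means with correlations of -0.069, -0.463, -0.061 and -0.202, and samples did not correlate best with their own number. So no pairing by number was seen. The homeostasis array 2 stood apart, with correlations from -0.463 to 0.383, and such a difference could hide a pairing. The replicate number was also the column of the slide. The block costs residual degrees of freedom.

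Leaving out 1 array in turn gave 7814 to 15052 changed genes, 4260 to 10212 higher, 3528 to 4840 lower, 8 to 11 lists higher and 8 lists lower in each run. The highest counts of genes came without the homeostasis array 2.

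An estimated correlation left 2 lists higher and 4 lower, and fry gave 14 and 9. Over the other alternatives the lists higher numbered 8 to 11 and the lists lower 8, or 9 with quantile normalization and without the homeostasis array 2. Of the single list results over all alternatives, 671 stayed on their side of the threshold, 25 lost their call and 17 gained it. Some lists and genes without a call turned direction within these counts, and 0 lists with a call did. NF-kB targets and fibroblast markers lost theirs without the homeostasis array 2 (adjusted p = 0.102 and 0.229). Of 123 named genes called, 103 kept their call in every alternative that tested them, including the one chosen after the data were seen. A gene that a filter removed, such as Lct with the filter on all 8 arrays, was not counted as lost there. The 2-fold minimum and the adjusted p under 0.01 were not applied to the named genes. Over named genes 2557 values stayed on their side of the threshold, 68 lost the call and 6 gained it. Gja1 was reversed with the mean of its probes, at 1.33 (adjusted p = 0.0218), since its probes disagree, and Gng13 was reversed at -0.0638 (adjusted p = 0.921) with quantile normalization and without the homeostasis array 2, where the cause was not tested.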

Other observations

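The 6 lists described here, and the genes named from them, were chosen after the data had been seen. The predictions on members whose values had not been seen were written before those values, except for the list of signals to intraepithelial lymphocytes, whose test was chosen only after the result was seen.

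Genes of the molecular clock and its output were mostly lower in atrophy. The time of day at which each group was collected is not among the sample values used here. Its part in this difference was therefore not tested. Of 19 measured members 12 fell and 1 rose (adjusted p = 1.7e-07 over 37 lists, and adjusted p = 0.0391 with an estimated correlation). Dbp, a clock-driven transcription factor gene, fell 15.2-fold from 4.06 ± 0.11 to 0.13 ± 0.17 (SD, n = 4, adjusted p = 8.86e-06), Per2 fell by 3.27 and Nr1d1 (REV-ERB alpha) fell by 2.27, while Nfil3, a repressor of clock output, rose by 2.63. Genes of glucose synthesis and fructose use also fell, 11 of 12 with 0 rising (adjusted p = 6.17e-11, and adjusted p = 0.0442 with an estimated correlation). Fbp1, fructose bisphosphatase, fell by 6.21, G6pc, glucose 6-phosphatase, fell by 5.89, and Khk, the kinase that starts fructose breakdown, fell by 3.34.

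Genes of stratified squamous epithelium, such as skin, rose in 14 of 26 members and fell in 0 (adjusted p = 0.00084), with adjusted p = 0.279 with an estimated correlation. Ly6d rose by 5.98 (adjusted p = 1.72e-05) and the keratin gene Krt23 rose by 3.99, and Krt5 and Krt14, keratins of the basal skin layer, had differences of -0.42 and 0.78 that did not pass. Genes of gastric epithelium rose in 6 of 14 members and 1 fell (adjusted p = 0.0343, and adjusted p = 0.438 with an estimated correlation), among them Cldn18, a claudin of stomach epithelium, up by 5.18, and Tff1, up by 5.82. Hypoxia and glycolysis genes rose in 7 of 24 members and fell in 9 (adjusted p = 0.271), with Hk2 and Hilpda up by 3.71 and 7.00, the latter well above background on 3 of 4 homeostasis arrays, while Egln3 fell by 1.82.

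The hypothesis for each list was that members not yet seen shift together. For the clock list the unseen members had a median of -1.02 (1 up and 10 down of 17), and for glucose synthesis and fructose use -2.07 (0 up and 8 down of 9). In both the unseen members may be read as moving with the seen ones. For squamous epithelium the median was 0.816 (8 up and 0 down of 20), which met the prediction. Dim genes in general also read higher in atrophy, with medians of 0.98 in the dimmest of 5 classes and 0.55 in the next. The unseen squamous members were not set against genes of the same levels, and the adjusted p of the list includes the seen members. A shared shift of the squamous list is therefore not decided. The gastric list gave 1.41 with 4 up and 1 down of 12, too few calls to decide. The hypoxia list gave -0.353 with 5 up and 9 down of 22, which argues against a shared shift.

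A candidate source of the fall in T lymphocyte markers was a lower level of epithelial signals to these cells. Il15 fell by 3.14 and the butyrophilin-like genes Btnl1 and Btnl6, which maintain gut gamma delta T cells, fell by 2.56 and 2.98, while the chemokine genes Cxcl9 and Cxcl16 rose by 3.16 and 1.49. Unseen members of this list went both ways, with a median of -0.652 and 3 up and 5 down of 9 (adjusted p = 0.431 for the list), so a uniform loss of such signals was not borne out, and a role of single members is untested.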
